A study of Mus musculus with 4 samples.

How the data were processed

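Total RNA from 4 populations of mouse CD4 T cells, taken from the spleen and lymph nodes of C57BL/6 mice of 8 to 10 weeks, cultured and sorted, was labelled with biotin from 1 µg per sample and hybridised to Affymetrix expression arrays, per the labels. Each population has 1 array. The values are signal intensities on a linear scale, deposited by the authors and made with MAS5, per the submitters' processing notes; its version is not given in the sources used here. MAS5 combines the probes of a probe set into a single signal and scales each array. After leaving out the lowest and highest 2% of probe sets, the mean deposited intensity was 100 on each of the 4 arrays, so the authors' scaling was used as deposited. The scanner files and the detection calls were not used here.

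The table holds 45101 probe sets, of which 64 are controls. Probe sets were named from the platform annotation, and symbols were updated through the gene identifier in a RefSeq gene table. Of the non-control probe sets, 34945 have 1 gene symbol, 932 have several and 9160 are unnamed here; those with several symbols named no gene. The gene identifier of 34741 of the single-gene probe sets was in the RefSeq table, and the other 204 kept the platform's symbol. No coordinates were used.

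The floor was the median signal of all non-control probe sets over the 4 arrays pooled, 12.1. Values below it were set to it before log2. A gene was represented by the single-gene probe set with the highest mean log2 value over the 4 arrays, which gave 18193 genes, 11769 of them above the floor on at least 1 array and 9010 with more than 1 probe set. With 1 array per group no test between groups was possible, so a gene was called higher or lower when the arrays differed by 2-fold or more and the higher array lay above the floor. A fold against a value below the floor is a lower bound and is written "at least". All 4 comparisons are of single arrays: exFoxp3Th17 with Th17, Th17 with Th0, exFoxp3Th17 with Treg, and Treg with Th0.

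The number of arrays limits the precision, and no spread between samples can be given. As a description of measurement noise within arrays, genes with 2 probe sets above the floor were used: the log2 ratios of the 2 probe sets differed with a robust SD of 0.38 to 0.45 across the 4 comparisons. The calling step was tested on simulated data made from each gene's mean log2 signal over the 4 arrays, for exFoxp3Th17 against Th17. The simulation covered 18193 genes with noise of SD 0.3 in log2 units. Changed genes were drawn only from those with a mean above 4 times the floor, so recovery of dimmer genes was not tested. The calling step called 25 of 50 genes changed 2-fold, 46 of 50 changed 3-fold, 50 of 50 changed 4-fold and 50 of 50 changed 8-fold in the right direction. It also called 152 of 17993 unchanged genes. These included genes below the floor, many of which the floor kept from being called. The simulated noise was the same at every signal level and held no differences between cultures, sorts or animals. The 152 calls therefore give no rate of false calls between the real arrays.

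The comparisons, the floor, the threshold, the 30 gene lists and the rule for naming genes were fixed before the data were examined. The lists hold 405 entries (362 genes), of which 358 (321 genes) have a single-gene probe set; 3 list symbols were updated. They cover CD4 T cell identity, helper and regulatory T cell programs, signalling responses, metabolism, cell cycle, stress, housekeeping and markers of other cell types. For each list the median log2 ratio over members above the floor on any array was set against 10000 random lists of the same size, matched on mean signal in 20 bins. The percentile describes these arrays and is not a p-value. A further 7 lists were chosen after the data were seen and are used only in the closing section.

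The rule named the sort markers Il17a and Foxp3, the 10 genes with the largest ratio in each direction of each comparison, up to 4 called members of each list, and Sox4, Tnfsf11, Ccr6, Ccl20 and Il23r, with which the study's published account dealt. A gene among the 10 needed a signal of at least 4 times the floor (48.4) on the higher array, no other probe set above the floor going the opposite way by 2-fold, and a symbol that is not a clone or predicted name. Il23r has no single-gene probe set here and was not analysed here, and 1 further gene of the rule is not reported here. The rule covers more genes than are named. Some genes printed lie outside it and were chosen after their values were seen: Kdm5d and Uty, the uncalled markers Cd79a, Ms4a1, Lyz2, S100a8, S100a9, Cd8a and Cd8b1, and in the closing section Hif1a, Vegfa, Bnip3, Igtp and Irgm1. The values of Plagl1, Ikzf2, Nt5e and Nrp1 in the main comparison were added in the same way.

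For genes with a 4-fold or larger difference between Th17 and Treg, the position of exFoxp3Th17 was its log2 distance from Treg divided by the log2 distance of Th17 from Treg. The alternatives tried were quantile normalization, a shift to equal medians of expressed probe sets, 0.5 times the floor (6.05), 2 times the floor (24.2), the floor added as a pseudocount, the mean of a gene's probe sets, leaving out probe sets that can bind several transcripts, and a 3-fold threshold. A floor of 4 times the main one was added after seeing the data. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.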

Results

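The series compared IL-17-producing T cells that arose from different precursors. The Th0 and Th17 populations came from naive CD4 T cells cultured without polarisation or under Th17 conditions, and the exFoxp3Th17 and Treg populations came from Foxp3+ CD4 T cells cultured under Th17 conditions or with IL-2. After culture, cells were sorted on a GFP reporter of IL-17 and on Foxp3: Th17 and exFoxp3Th17 were IL-17 positive and Foxp3 negative, Th0 was negative for both, and Treg was Foxp3 positive and IL-17 negative. Each population was measured on 1 array, without replicates, so every difference below is a difference between 2 arrays. Between 48.7% and 51.2% of probe sets lay above the floor of 12.1 on each array.

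The sort markers were read first. Foxp3, the transcription factor that defines regulatory T cells, had a signal of 584.9 in Treg and lay below the floor in Th0 (4.3), Th17 (6.2) and exFoxp3Th17 (8.0), as gated. Il17a lay below the floor on all 4 arrays, with signals of 7.1 in Th0, 9.8 in Th17, 9.4 in exFoxp3Th17 and 8.2 in Treg, so its single probe set did not separate the IL-17 positive from the IL-17 negative gates. Il21, another Th17 cytokine, reached 491.0 in Th17 and 339.1 in exFoxp3Th17 and lay below the floor in Th0 (1.5) and Treg (1.7).

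The arrays also differed in sex-linked transcripts, and the labels used here give no sex. Xist, the RNA that silences an X chromosome in female cells, had a signal of 3766 in exFoxp3Th17 and of 7.4 in Th0, 7.7 in Th17 and 10.8 in Treg. The Y-linked gene Eif2s3y was at 4.7 in exFoxp3Th17, against 747.3, 875.8 and 654.5 in Th0, Th17 and Treg. Kdm5d (2.9 against 133.0 to 219.7) and Uty (0.7 against 107.3 to 161.7) went the same way. Every comparison with exFoxp3Th17 therefore also crosses this difference. Ratios of 3' to 5' control probe sets, a sign of RNA integrity, were 0.91 to 1.06 for Gapdh and 1.12 to 1.31 for Actb.

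**Figure D1:**
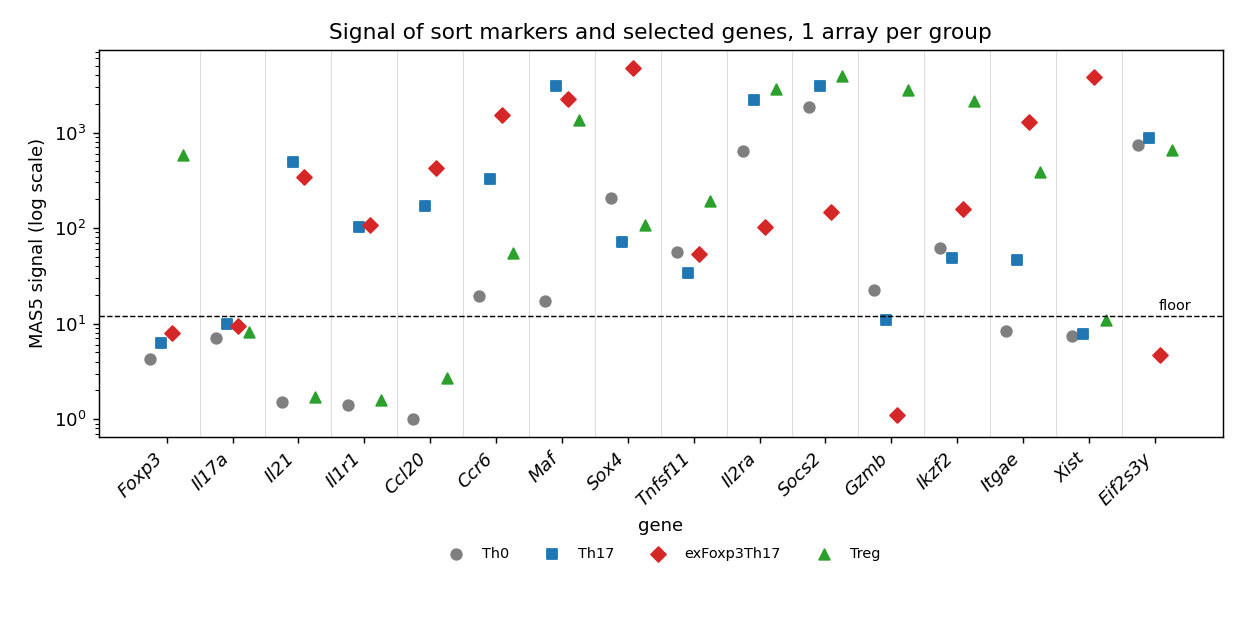
MAS5 signal on a log axis for the sort markers and 14 other genes, with 1 point per array (Th0, Th17, exFoxp3Th17, Treg) and a dashed line at the floor of 12.1. Foxp3 is above the floor only in Treg, Il17a on no array, and Sox4 and Xist are highest in exFoxp3Th17 (4788 and 3766).

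The main comparison set exFoxp3Th17 against Th17, cells of the same culture and gate but different origin. Sox4, an HMG-box transcription factor, had a signal of 4788 in exFoxp3Th17 and 71.6 in Th17, a 66.9-fold difference, and its 5 other probe sets above the floor were each higher by 2-fold or more. Itgae, the integrin alpha E chain (CD103) of intraepithelial and regulatory T cells, was 27.8-fold higher (1298 against 46.7), and the chemokine receptor Ccr6 was 4.6-fold higher (1522 against 328.5). In the other direction, the transglutaminase gene Tgm2 was 172-fold lower (21.5 against 3704), Il10 was at least 33.7-fold lower (12.0 against 407.7) and Il2ra, the alpha chain of the IL-2 receptor, was 21.2-fold lower (102.6 against 2178). Gene groups for the response to IL-2, for glycolysis and for the cell cycle were lower in exFoxp3Th17, while the Th17 program was divided.

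In all, 880 genes were higher and 856 lower in exFoxp3Th17 than in Th17, with 10033 within 2-fold. The side with more calls depended on the processing: the lower calls were more under quantile normalization (778 higher, 931 lower) and with equal medians of expressed probe sets (795 and 928). They were also more at 2 times the floor (694 and 703), at 4 times the floor, with the floor as a pseudocount (651 and 722), with the mean of a gene's probe sets (729 and 739) and at 3-fold. At 8-fold or more the counts were 36 higher and 75 lower. Where a called gene had a second probe set above the floor, it went in the same direction for 415 of 434 genes called higher and 383 of 398 called lower, and by 2-fold or more for 223 and 247. Besides Sox4, Itgae and Xist (at least 311-fold), the largest differences upward were in Rasgrp3, which encodes an activator of Ras (at least 35.7-fold), the dynamin gene Dnm3 (26.9-fold), the sialyltransferase St8sia6 (21.6-fold), the cholesterol exporter Abca1 (20.9-fold, 1777 against 84.9), the protease Capn3 (19.9-fold), Atp6v0d2, a subunit of the vacuolar proton pump (16.8-fold), and the alcohol dehydrogenase Adh1 (12.7-fold). Downward they were Plac8 (78.6-fold, 14.4 against 1133), the inhibitory NK receptor gene Klrc1 (51.6-fold), the cytokine Il24 (at least 46.9-fold), the galectin Lgals3 (42.2-fold), the actin regulator Enah (40.1-fold), the protein C receptor Procr (38.9-fold) and Serpinf1 (at least 32.1-fold), along with Y-linked Eif2s3y (at least 72.4-fold).

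Of 13 measured members of the Th17 program, 4 were higher, 3 lower and 6 within 2-fold, with a median log2 ratio of 0.06 at percentile 47.9 of the random lists. The higher members were Ccr6, Tmem176a (4.1-fold, 2710 against 664.4), Tmem176b (3.6-fold) and Ccl20, the ligand of Ccr6 (2.5-fold, 426.9 against 169.2). Irf4, a transcription factor induced by T cell receptor signals, was 13.1-fold lower (80.3 against 1055). In the pathogenic Th17 signature, 2 of 12 members were higher, 2 lower and 8 neither (median 0.07, percentile 43.1), with Casp1 5.6-fold higher and Csf2, which encodes GM-CSF, at least 5.1-fold lower. The non-pathogenic signature had 2 of 8 higher, 3 lower and 3 neither (median -0.53, percentile 0.37). Its lower members included Il10 and Il9 (21.0-fold, 38.8 against 813.2) and its higher ones were Ikzf3 (2.6-fold) and Il6st (2.5-fold); neither of those had another probe set that differed by 2-fold in that direction.

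The regulatory T cell signature was lower as a group in exFoxp3Th17 than in Th17, although these cells came from Foxp3+ precursors. Of its 22 measured members, 5 were higher, 10 lower and 7 neither (median -0.49, percentile 0.05). Itgae was the largest of the higher ones, and the others were Plagl1 (6.4-fold), Ikzf2 (3.3-fold), Nt5e (2.1-fold) and Nrp1 (2.0-fold). Il10, Il2ra and Socs2 (20.5-fold, 148.9 against 3052) led the lower ones. Both Il2ra and Socs2 also belong to the IL-2 and STAT5 response list. The signature was itself higher in Th17 than in Th0, with 12 of 22 members higher. Its lower level here therefore need not mean less regulatory identity. Among HMG-box factors, Sox4, Tox (5.6-fold) and Tox2 (5.6-fold, 2150 against 383.2) were higher, none was lower and 6 were neither (median 0.62, percentile 99.3). The follicular helper program had 4 of 10 higher and 6 neither (median 0.37, percentile 94.0), including the receptor Cxcr5 (at least 11-fold), Pdcd1 (3.8-fold) and Bcl6 (2.0-fold). Chemokine receptors had 5 of 14 higher, 1 lower and 8 neither (median 0.56, percentile 99.8). Ccr2 was the lower one (at least 5.6-fold), although 1 of its 2 other probe sets above the floor was at a log2 ratio of -0.1. For TGF-beta response genes these were 4 of 13 higher, 1 lower and 8 neither (median 0.60, percentile 99.4), with the receptors Tgfbr1 (3.9-fold) and Tgfbr2 (2.5-fold) higher; the other probe set of Tgfbr1 above the floor was at a log2 ratio of 0.51.

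Activation and growth groups ran lower in exFoxp3Th17. In the IL-2 and STAT5 response list, 10 of 14 genes were lower, 4 neither and none higher (median -1.88, percentile 0.0), led by Il2ra, Socs2 and Cdkn1a (9.5-fold). In glycolysis, 13 of 15 were lower and 2 neither (median -1.74, percentile 0.0), among them hexokinase Hk2 (8.4-fold, 98.9 against 835.3) and the glucose transporters Slc2a3 (7.8-fold) and Slc2a1 (7.4-fold). Of the 3 other probe sets of Slc2a3 above the floor, 1 was lower by 2-fold or more, and the highest was at a log2 ratio of -0.51. In the cell cycle list, 11 of 21 were lower and 10 neither (median -1.09, percentile 0.0), with the replication licensing gene Mcm2 at 4.7-fold and the mitotic kinase gene Aurkb at 4.4-fold. Cholesterol synthesis had 6 of 15 lower and 9 neither (median -0.63, percentile 0.06), and stress and immediate early genes had 7 of 17 lower and 10 neither (median -0.99, percentile 0.0), with Ier3 16.8-fold lower. For the STAT3 and IL-6 response these were 1 of 13 higher, 5 lower and 7 neither (median -0.55, percentile 0.18), with Pim1 7.6-fold and Myc 4.4-fold lower. Housekeeping genes had 1 of 10 lower, the transferrin receptor Tfrc (3.3-fold), and 9 neither (median 0.19).

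Mediators of bone and joint inflammation had 1 of 8 higher, Ccl20, 3 lower and 4 neither (median -0.27, percentile 8.78). Tnf was 15.3-fold lower (13.3 against 204.4) and Lta 8.2-fold lower. Tnfsf11, which encodes the osteoclast differentiation factor RANKL, was not called, with signals of 53.5 in exFoxp3Th17 and 33.5 in Th17. Th1 genes were 3 of 12 higher, 1 lower and 8 neither (median 0.00), with Il18r1 4.8-fold higher, and Th2 genes 2 of 6 higher, 3 lower and 1 neither (median -1.02, percentile 0.33), with Gata3 5.0-fold higher. Inhibitory receptors had 2 of 9 higher, 1 lower and 6 neither, and type I interferon response genes 1 of 14 higher and 13 neither. Naive and central memory genes had 1 of 12 higher and 2 lower while their median was above 0 (0.37, percentile 98.1). CD4 T cell identity genes were all 10 within 2-fold, with a median above the middle 95% of random lists (0.38, percentile 99.2).

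**Figure D2:**
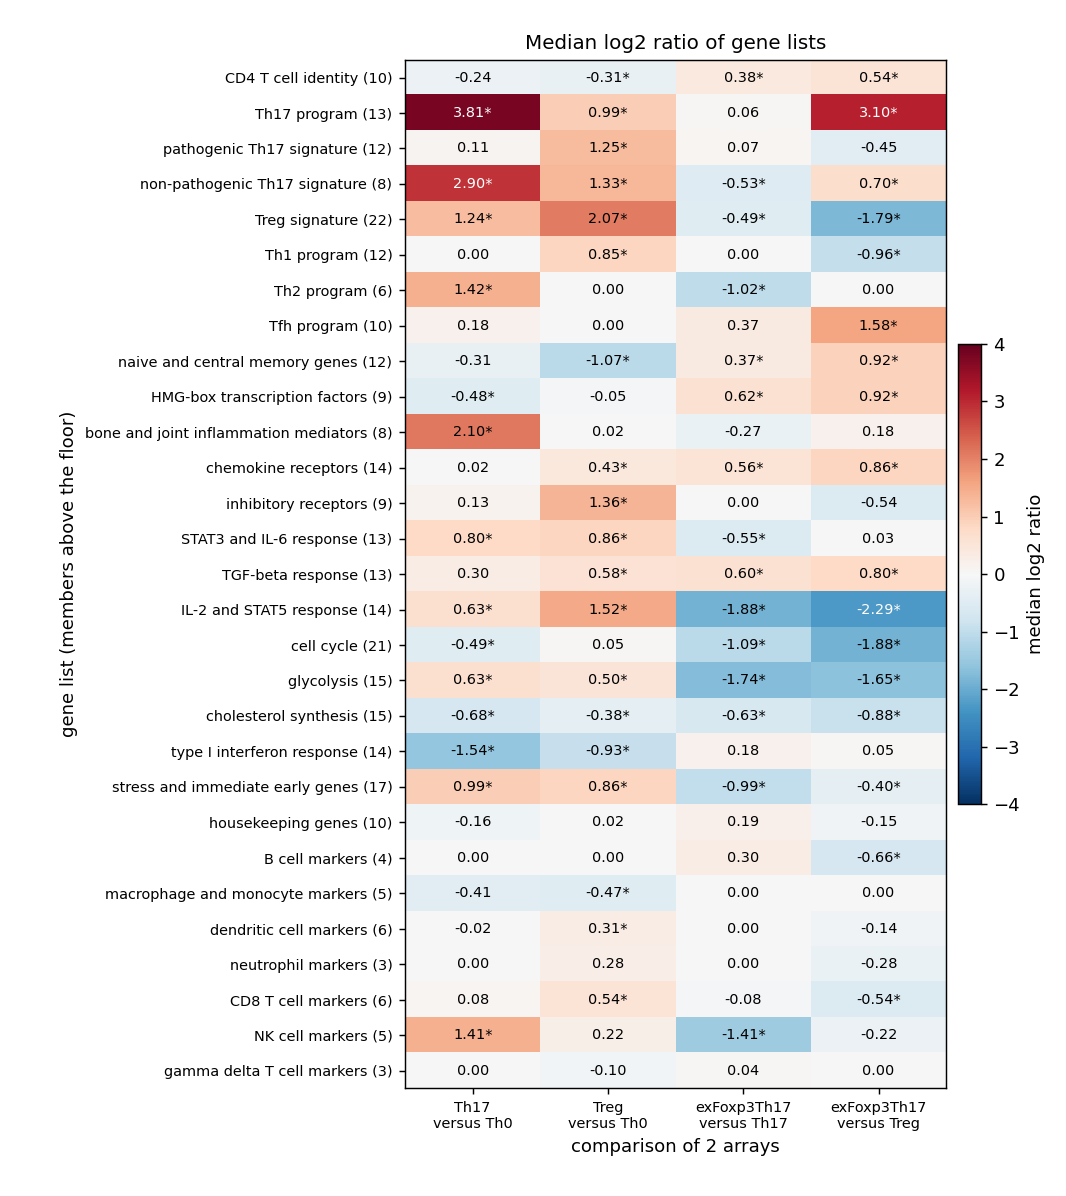
Median log2 ratio (colour and number) of each gene list (vertical, with its number of members above the floor) in each of the 4 comparisons of 2 arrays (horizontal). An asterisk marks a median outside the middle 95% of 10000 matched random lists; the IL-2 and STAT5 list is at -1.88 in exFoxp3Th17 versus Th17 and at 1.52 in Treg versus Th0.

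Th17 against Th0 compared the culture conditions, with the IL-17 gate, in cells from naive precursors. The Th17 program was higher almost throughout: 12 of its 13 measured members were higher and 1 was neither (median 3.81, percentile 100). Maf, a transcription factor of Th17 and IL-10-producing T cells, was 178-fold higher (3072 against 17.2, with all 4 other probe sets), the cytokine Il21 at least 40.6-fold, and Ccr6 16.7-fold (328.5 against 19.6). The aryl hydrocarbon receptor gene Ahr was 40.2-fold higher by its brightest probe set, but its other probe set above the floor was at a log2 ratio of 0.90, less than 2-fold. Type I interferon response genes were lower, 9 of 14 with 5 neither (median -1.54, percentile 0.0), among them Rtp4 (15.3-fold) and Ifit1 (at least 6.3-fold).

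The counts were 968 higher and 810 lower, and at 8-fold or more 134 and 47. With 0.5 times the floor the lower calls were more (1182 higher, 1221 lower). A second probe set went in the same direction for 433 of 463 genes called higher and 351 of 367 called lower, and by 2-fold or more for 262 and 190. The largest increases besides Maf were in Tgm2 (at least 306-fold, 3704 against 7.4), Ctla2b (145-fold), the protease inhibitor Serpinb1a (at least 112-fold), Klrc1 (at least 99.2-fold), the homing receptor Gpr15 (at least 95.9-fold), the metallothionein Mt2 (93.8-fold), Timp1 (at least 80.3-fold), Il9 (at least 67.2-fold, 813.2 against 9.7) and the cathepsin Ctsw (66.5-fold). The largest decreases were in Dapl1 (169-fold, 14.9 against 2522), Pdlim4 (at least 79.1-fold), the integrin beta chain Itgb3 (44.0-fold), Trat1, an adaptor of the T cell receptor (41.6-fold), Sytl2 (23.4-fold), Ifit1bl1 (at least 21.7-fold), Clec2i (20.5-fold), Ms4a4c (at least 17.9-fold), Itih5 (17.0-fold) and Akr1c12 (at least 16.8-fold).

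The regulatory T cell signature had 12 of 22 higher in Th17 than in Th0 and 10 neither (median 1.24, percentile 100), among them Il10 (at least 33.7-fold) and the ectoenzyme Nt5e (8.1-fold). The non-pathogenic signature had 4 of 8 higher, 1 lower and 3 neither (median 2.90). The pathogenic signature was divided, with 4 of 12 higher, 2 lower and 6 neither and a median inside the middle 95% of random lists (0.11, percentile 81.2); Csf2 was at least 5.1-fold and Icos 3.5-fold higher. Bone and joint mediators had 6 of 8 higher and 2 neither (median 2.10, percentile 100), including Ccl20 (at least 14-fold), Tnf (6.8-fold) and Lta (6.3-fold); Tnfsf11 was not called (33.5 against 56.8). STAT3 and IL-6 response genes had 6 of 13 higher, 1 lower and 6 neither (median 0.80), with Fosl2 29.4-fold higher, and stress and immediate early genes 6 of 17 higher and 11 neither (median 0.99), with Ier3 52.4-fold and Asns 17.9-fold higher. The IL-2 and STAT5 list had 5 of 14 higher, 1 lower and 8 neither (median 0.63), and glycolysis 4 of 15 higher and 11 neither (median 0.63), Hk2 by 6.9-fold.

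In the cell cycle list 5 of 21 genes were lower in Th17 and 16 neither (median -0.49, percentile 0.01), and in cholesterol synthesis 1 of 15 was lower and 14 neither (median -0.68, percentile 0.01). HMG-box factors had 2 of 9 higher, 2 lower and 5 neither (median -0.48, percentile 1.96): Tox2 was 22.8-fold higher, while Tox was 4.6-fold and Sox4 2.9-fold lower (71.6 against 205.9). In the Th2 list Gata3, which directs Th2 differentiation, was 16.8-fold lower (27.0 against 452.5), although 3 of the 6 members were higher and the median was 1.42. Naive and central memory genes had 5 of 12 lower and 7 neither, with a median inside the middle 95% (-0.31, percentile 3.76) and the migration regulator Klf2 4.9-fold lower.

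The comparison of exFoxp3Th17 with Treg asked how Th17 conditions, with the change of gate, altered cells of Foxp3+ origin. The Th17 program was higher in exFoxp3Th17, 8 of 13 members with 1 lower and 4 neither (median 3.10, percentile 100), and the regulatory T cell signature was lower, 14 of 22 members with 3 higher and 5 neither (median -1.79, percentile 0.0). Ccr6 was 27.9-fold higher (1522 against 54.5), Ccl20 at least 35.3-fold and Il21 at least 28.0-fold, whereas the granule protease Gzmb was at least 230-fold lower (1.1 against 2781), Il2ra 28.0-fold lower and the activation receptor Tnfrsf9 at least 28.1-fold lower. All 21 measured cell cycle genes were lower. This comparison shares its exFoxp3Th17 array with the main comparison.

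Here 1328 genes were higher and 1170 lower, the most of the 4 comparisons, and 95 and 80 at 8-fold or more. Here the side with more calls changed with the scaling alone, to 1192 higher and 1269 lower under quantile normalization and 1157 and 1291 with equal medians. Second probe sets went in the same direction for 640 of 684 genes called higher and 525 of 542 called lower, and by 2-fold or more for 377 and 367. After Xist (at least 311-fold), the largest increases were in Tox2 (80.9-fold, 2150 against 26.6), the receptor-activity modifying protein Ramp1 (50.9-fold), Sox4 (44.5-fold, 4788 against 107.7), Tmem176a (42.9-fold), Crispld2 (at least 40.4-fold), Tgfbi (at least 39.6-fold), Sestd1 (34.8-fold) and Il17re, a receptor of the IL-17 family (34.5-fold). The largest decreases, besides Gzmb and the gated Foxp3 (at least 48.3-fold), were in the interferon-inducible Ifitm3 (119-fold, 13.7 against 1624), Itih5 (91.5-fold), Lgals3 (76.2-fold), Eif2s3y (at least 54.1-fold), Coro2a (44.8-fold), the GTPase Iigp1 (42.3-fold), Ifitm1 (40.5-fold) and Plac8 (37.9-fold).

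The IL-2 and STAT5 response had 13 of 14 genes lower and 1 neither (median -2.29, percentile 0.0), with Prdm1, the gene of Blimp-1, at least 34.9-fold and Socs2 26.1-fold lower; Treg cells were cultured with IL-2. Cell cycle genes had a median of -1.88 (percentile 0.0), with Mcm2 7.1-fold lower, glycolysis 11 of 15 lower and 4 neither (median -1.65, percentile 0.0), with Slc2a1 5.7-fold lower, and cholesterol synthesis 7 of 15 lower and 8 neither (median -0.88). Stress and immediate early genes had 1 of 17 higher, 5 lower and 11 neither (median -0.40, percentile 0.8). Th1 genes had 2 of 12 higher, 6 lower and 4 neither (median -0.96, percentile 0.03), including Nkg7 (at least 16-fold) and Tbx21 (at least 7.2-fold) among the lower. The pathogenic Th17 signature had 3 of 12 higher, 5 lower and 4 neither (median -0.45, percentile 2.92), and the non-pathogenic 2 of 8 higher, 1 lower and 5 neither (median 0.70).

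Follicular helper genes were higher, 6 of 10 with 4 neither (median 1.58, percentile 100), among them Pou2af1 (at least 20.1-fold), Cxcr5 (at least 11-fold) and Bcl6 (9.4-fold). HMG-box factors had 3 of 9 higher, 1 lower and 5 neither (median 0.92, percentile 99.9), chemokine receptors 6 of 14 higher, 2 lower and 6 neither (median 0.86), with Gpr15 17.9-fold higher and Ccr2 at least 18.3-fold lower, and TGF-beta response genes 6 of 13 higher, 2 lower and 5 neither (median 0.80). Naive and central memory genes had 6 of 12 higher, 3 lower and 3 neither (median 0.92, percentile 99.99), with the IL-7 receptor gene Il7r 10.3-fold higher (3049 against 297.4) and Klf3 14.8-fold lower. Among bone and joint mediators 3 of 8 were higher, 3 lower and 2 neither (median 0.18); Tnfsf11 was 3.6-fold lower (53.5 against 190.2), with its other probe set above the floor at -0.95. CD4 T cell identity genes had a median of 0.54 (percentile 99.8), with Cd4 higher (2.0-fold, 98.1 against 48.3) and the other 9 within 2-fold.

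Treg against Th0 compared IL-17 negative cells of the 2 origins, which also differed in culture and in the Foxp3 gate. The regulatory T cell signature was higher in Treg, 19 of 22 members with 3 neither (median 2.07, percentile 100). Beside the gated Foxp3 (at least 48.3-fold), the transcription factor Ikzf2 was 34-fold higher (2115 against 62.2), Itgae at least 31.8-fold and Tnfrsf9 12.6-fold. IL-2 and STAT5 response genes were also higher, 10 of 14 with 4 neither (median 1.52, percentile 100), with Gzmb 123-fold higher (2781 against 22.5). Naive and central memory genes were lower, 6 of 12 with 6 neither (median -1.07, percentile 0.0), including Dapl1 (28.3-fold), Il7r (4.3-fold) and Satb1 (4.2-fold).

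This pair had the fewest calls, 654 higher and 582 lower, and 56 and 18 at 8-fold or more; second probe sets went in the same direction for 280 of 301 and 242 of 261 of them, and by 2-fold or more for 166 and 124. Other large increases were in Maf (78.5-fold), Mt2 (56.2-fold), Serpinb1a (at least 42.6-fold), Iigp1 (28.0-fold), Mt1 (26.9-fold) and Ifitm1 (25.9-fold). Decreases were led by Pdlim4 (at least 79.1-fold), Tdrp (at least 31.3-fold), the phosphodiesterase Pde3b (18.6-fold), Adh1 (13.5-fold), the neuropeptide receptor Vipr1 (at least 10.9-fold), Ms4a4c (10.0-fold), Snn (9.7-fold), Tgfbr3 (9.4-fold) and Hemgn (9.1-fold). Th1 genes had 5 of 12 higher, 1 lower and 6 neither (median 0.85), with Cxcr3 23.1-fold higher, and inhibitory receptors 5 of 9 higher, 1 lower and 3 neither (median 1.36), with Ctla4 3.7-fold higher. The pathogenic Th17 signature had 6 of 12 higher, 2 lower and 4 neither (median 1.25, percentile 100), its largest median of the 4 comparisons. The non-pathogenic signature had 4 of 8 higher, 1 lower and 3 neither (median 1.33). Both arrays were of IL-17 negative cells. Type I interferon genes had 7 of 14 lower and 7 neither (median -0.93, percentile 0.0). Tnfsf11 was 3.4-fold higher (190.2 against 56.8), and all 21 cell cycle genes were within 2-fold (median 0.05). CD4 T cell identity genes had a median of -0.31 (percentile 0.77), with Cd4 2.3-fold lower (48.3 against 109.6) and 9 neither; in both calls of Cd4 its other probe set above the floor differed by less than 2-fold.

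The effect of Th17 conditions was then compared between the origins, in pairs that share no array. Both pairs also differed in the IL-17 gate, and exFoxp3Th17 versus Treg in the Foxp3 gate, in IL-2 culture and in sex-linked transcripts. Of the genes called in both Th17 versus Th0 and exFoxp3Th17 versus Treg, 291 were higher in both, where 109.2 would be shared by independent lists, and 198 were lower in both (80.5 for independent lists). Opposite calls were also above those of independent lists, 160 genes higher from naive and lower from Foxp3+ cells (96.2) and 137 the reverse (91.4). Across genes, which are not independent replicates, Pearson's r was 0.14 and Spearman's rho 0.09. Tmem176a, Ccr6, Ccl20, Il21 and Gpr15 were higher in both, while Tgm2, Plac8 and Il10 were higher in Th17 than Th0 and lower in exFoxp3Th17 than Treg, and Sox4 was the reverse.

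The effect of origin was compared the same way between exFoxp3Th17 versus Th17 and Treg versus Th0. Here 70 genes were higher in both (48.9 for independent lists), 30 were lower in both (42.3), and 352 were called in opposite directions, 174 higher under Th17 conditions and lower otherwise (43.5) and 178 the reverse (47.6). Pearson's r across genes was -0.29 and Spearman's rho -0.31. Itgae was higher by origin in both, while Tgm2, Plac8, Il2ra and Il10 were lower in exFoxp3Th17 than Th17 and higher in Treg than Th0. Treg and Th0 also differed in the Foxp3 gate and in culture, with IL-2 for Treg. The exFoxp3Th17 and Th17 arrays also differed in sex-linked transcripts. Neither the opposite calls nor the negative correlation can therefore be assigned to origin.

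**Figure D3:**
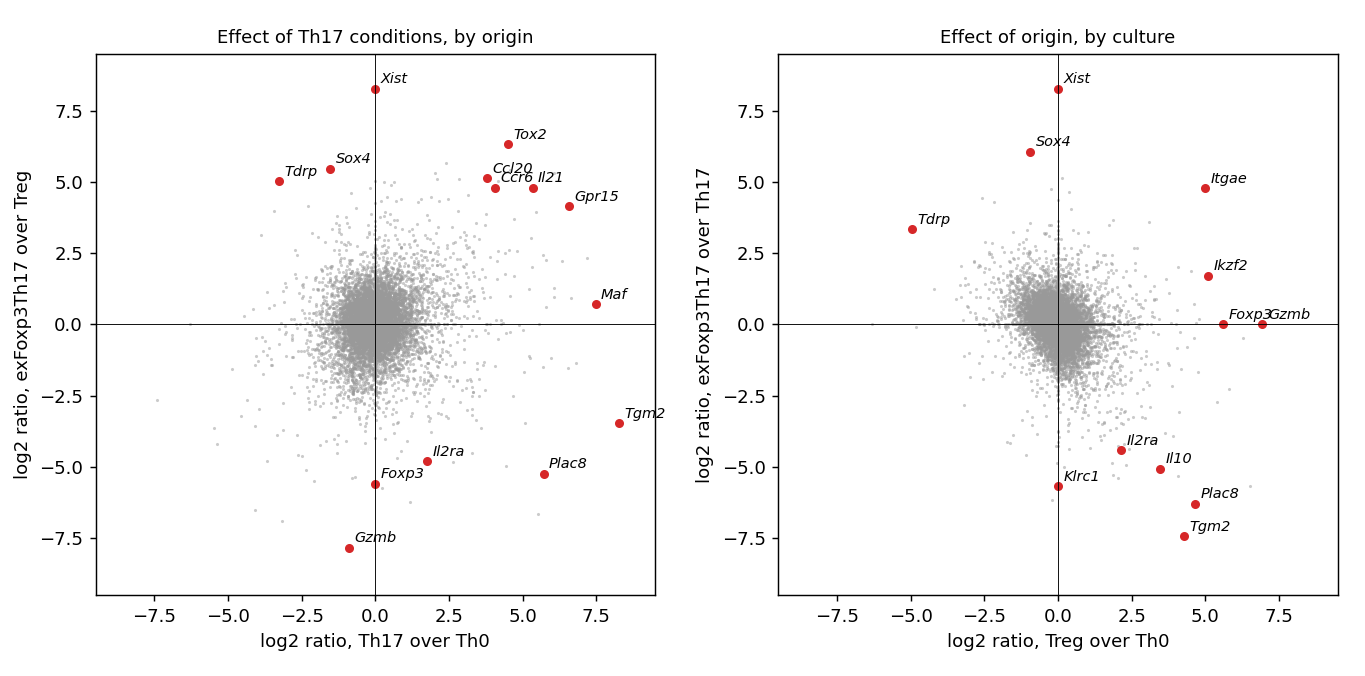
Log2 ratios of genes above the floor on any array, 1 grey point per gene, for Th17 conditions in cells of naive origin (horizontal) and Foxp3+ origin (vertical) on the left, and for origin outside (horizontal) and under (vertical) Th17 conditions on the right; genes in red are named. Pearson's r across genes is 0.14 on the left and -0.29 on the right. Treg and Th0 also differ in culture and in the Foxp3 gate.

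Between Treg and Th17, exFoxp3Th17 lay nearer to Th17 for most genes that separated the 2 by 4-fold or more. On a scale from 0 (Treg) to 1 (Th17), the median position was 0.734 over 156 genes higher in Th17 (quartiles 0.266 and 1.105) and 0.861 over 122 genes higher in Treg (quartiles 0.478 and 1.0). Of the former 98 and of the latter 91 were nearer to Th17, while 56 and 30 lay beyond the Th17 value. Values below the floor were set to it. Genes higher in Treg with Th17 below the floor therefore could not lie beyond Th17. Where exFoxp3Th17 was below the floor too, such a gene scored exactly 1 and counted as nearer to Th17. Absence of a Treg transcript alone thus gives this position, and the position of Th0 was not computed.

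Markers of other cell types were read on all arrays. Cd79a, Ms4a1, Lyz2, S100a8 and S100a9 lay below the floor on each array, and Cd8a was at 11.1 to 14.3. Others were above it. Cd8b1 was at 64.6 in Th0, 83.5 in Th17, 64.9 in exFoxp3Th17 and 51.7 in Treg and was not called. The B cell factor Ebf1 was at 30.1 in Th17 and below the floor elsewhere (at most 9.6), a call of at least 2.5-fold against exFoxp3Th17 and against Th0 that its 2 other probe sets above the floor did not share at 2-fold. Ighm, an immunoglobulin gene of B cells, was at 3316 in Th0, 2406 in Treg, 958.5 in exFoxp3Th17 and 806.8 in Th17, and was called lower in Th17 than Th0 (4.1-fold) and in exFoxp3Th17 than Treg (2.5-fold). Cd79b was at 55.6 in Treg, 19.3 in exFoxp3Th17, 9.6 in Th0 and 5.0 in Th17, higher in Treg than Th0 (at least 4.6-fold) and lower in exFoxp3Th17 than Treg (2.9-fold). Ctss, a cathepsin of antigen-presenting cells, was at 3557 in exFoxp3Th17, 2307 in Th17, 1698 in Treg and 1482 in Th0, and was 2.1-fold higher in exFoxp3Th17 than Treg. B cell markers had medians of 0.30, 0.00, -0.66 and 0.00 in exFoxp3Th17 versus Th17, Th17 versus Th0, exFoxp3Th17 versus Treg and Treg versus Th0, over 4 members. In the same order, medians were 0.00, -0.41, 0.00 and -0.47 for 5 macrophage and monocyte markers, 0.00, -0.02, -0.14 and 0.31 for 6 dendritic cell markers, 0.00, 0.00, -0.28 and 0.28 for 3 neutrophil markers, -0.08, 0.08, -0.54 and 0.54 for 6 CD8 T cell markers, and 0.04, 0.00, 0.00 and -0.10 for 3 gamma delta T cell markers. NK cell markers were at -1.41, 1.41, -0.22 and 0.22 over 5 members, the largest medians of these lists in the 2 comparisons with Th17: Klrd1 was at 1801 in Th17, 504.3 in exFoxp3Th17, 256.1 in Th0 and 32.1 in Treg. The class II gene H2-Ab1 was at 219.8 in Th17, 131.7 in Treg, 29.9 in Th0 and 19.7 in exFoxp3Th17, and Cd74, its partner in antigen presentation, at 16.7 to 41.4. Only 2 erythroid markers were above the floor on any array, and neither was called.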

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

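Of the tests in this part, those of a mixed-sex pool, of the donors' sex behind the activation lists, of exchanged arrays, of a failed sort and of the Il17a probe set, and the count of sex-linked probe sets above 2 times the floor, were chosen only after their results were seen.

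The first pattern is the low level of activation and growth lists in exFoxp3Th17 compared with Th17. For a difference in scaling, quantile normalization and the shift by expressed probe sets were tried. The highest of the IL-2 and STAT5, glycolysis and cell cycle medians was then -1.06. Both moved the median log2 ratio over genes above the floor only from 0.034 to 0.0. They could therefore hardly have raised these lists, and the test shows only that the lists were low under each scaling tried. Degraded RNA is argued against by a 3' to 5' ratio that differed by at most 0.20 log2 units. A lower state of activation and growth predicted movement in 2 lists not read before: MYC targets and ribosome biogenesis had 14 of 22 genes lower (median -1.18, percentile 0.0) and quiescence genes 8 of 15 higher (median 1.03, percentile 100). Myc and the cell cycle list had already been read as lower on the same arrays, so this movement was likely beforehand and adds little. The lists may reflect less active cells at harvest, which leaves open whether origin, growth in culture, sorting or the identity of the sample was responsible. The sex of the donors stays open because 0 arrays of the other sex share this origin and culture.

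The second pattern is the female pattern of sex-linked transcripts on the exFoxp3Th17 array alone. A pool of both sexes is argued against by a summed Y-linked signal of 0.77% of the mean of the other arrays. For failure of single probe sets, 7 of 8 probe sets of Xist and Y-linked genes (87.5%) went the female way by 2-fold against all 3 other arrays, which is short of the 90% set beforehand; the eighth, for Uty, had signals of 21.6, 12.3, 0.1 and 9.3 in Th0, Th17, exFoxp3Th17 and Treg, and the 7 above 2 times the floor all went that way. Female donors for this array alone predicted higher X genes that escape inactivation, and their lowest median was 0.29, but the same genes had a median of 0.27 between Th17 and Th0, so this test separates little. The pattern may come from the donors or from the identity of the sample, and either way every exFoxp3Th17 comparison carries it.

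The third pattern is Il17a below the floor in both IL-17 positive gates. An exchange of an IL-17 positive array with an IL-17 negative array is argued against by the rest of the Th17 program: without Il17a, 12 of 13 measured members were higher in Th17 than Th0 and 8 of 13 in exFoxp3Th17 than Treg. Between the IL-17 negative arrays, 6 of 13 members were higher in Treg than Th0 and 7 neither (median 0.99). The program therefore did not follow the IL-17 gate alone. A failed IL-17 sort stays open, since the culture changes with the gate and 0 arrays of the other IL-17 gate share an origin and culture. As labelled, Ikzf2 was at 158.1 in exFoxp3Th17 and 48.2 in Th17, and at 2115 in Treg and 62.2 in Th0. Itgae was at 1298 and 46.7, and at 384.3 and 8.3, in the same order. Both were thus higher by origin in both cultures, which goes with the labels. However, 10 of 22 regulatory T cell signature members were lower in exFoxp3Th17 than in Th17, and 5 higher. An exchange of the 2 arrays cultured under Th17 conditions therefore stays open too. Such an exchange would turn every ratio of the main comparison (to 856 higher and 880 lower), the 352 opposite calls by origin would become the same way, and the median positions between Treg and Th17 would be 0.444 and 0.340. By Th17 conditions, 480 genes would be called the same way and 67 in opposite ways, against 489 and 297 as labelled. Calls in exFoxp3Th17 versus Treg would fall to 619 higher and 513 lower. Those in Th17 versus Th0 would rise to 1168 and 991. A reporter allele that does not make the Il17a transcript and a probe set that does not respond cannot be told apart, since the highest Il17a signal on any array was 9.8 and the gene has 1 probe set; no biological explanation was tested.

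Other results stood out because a gene, or the median of a list, moved oppositely with Th17 conditions in cells of naive and Foxp3+ origin. With single arrays the difference was not tested. Such moves also depend on the exchange left open above, with which 67 genes rather than 297 would be called in opposite ways. The difference of the log2 ratios (Th17 over Th0 minus exFoxp3Th17 over Treg) was 10.96 for Plac8, 9.39 for Enah, 8.10 for Mt2, 7.43 for Lgals3 and 6.43 for Mt1. With an array below the floor it was a bound: at least 11.72 for Tgm2, at least 8.54 for Il10, at least 8.14 for Serpinb1a and at least 7.14 for Procr. It was negative for Adh1 (-7.43), St8sia6 (-7.01), Sox4 (-7.00), Capn3 (-6.47) and Snn (-5.35), and for Tdrp (-8.31 or lower) and Vipr1 (-4.34 or lower), which lay below the floor in Treg. For the medians of lists it was 3.03 for the Treg signature, 2.93 for the IL-2 and STAT5 response, 2.28 for glycolysis, 1.39 for stress and immediate early genes and -1.40 for HMG-box transcription factors. Members of the HMG-box list went both ways in Th17 versus Th0 (2 higher, 2 lower), and Tox2 was higher in both comparisons. Among the 9160 probe sets unnamed here, which no comparison used, 74 were higher in Th17 than in the Th0 control and 303 were higher in Th0.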

How the results depend on the processing

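The alternative with 4 times the floor was chosen only after the data were seen; the others were planned. Of 106 counts and positions recomputed, 82 stayed within 1.5 times the main count (0.1 for positions) and 24 moved; quantile normalization, equal medians, the pseudocount, 2 times the floor and leaving out less specific probe sets moved none of them. Of 888 list medians 828 stayed within the probe set spread, 59 moved and 1 reversed: dendritic cell markers in Treg versus Th0 went to -0.04 without less specific probe sets, and the cause was not tested. Of 2839 ratios of named genes 610 moved and none reversed, mostly at other floors or with a pseudocount. With 0.5 times the floor, genes in Th17 versus Th0 came to 1182 higher and 1221 lower, which turns the balance, lower in Treg than Th0 to 888 and called the same way by origin to 168. With the mean of a gene's probe sets, 65 genes were called the same way by origin and the position over genes higher in Th17 was 0.591; the cause was not tested. At 3-fold, by construction fewer genes pass: 304 higher and 341 lower in exFoxp3Th17 than Th17, 475 and 275 in Th17 than Th0, 555 and 539 in exFoxp3Th17 than Treg, 301 and 169 in Treg than Th0, 170 the same way by Th17 conditions and 32 by origin. With 4 times the floor, which removes dim genes, 518 were higher in exFoxp3Th17 than Th17, 580 higher and 484 lower in Th17 than Th0, 864 and 774 in exFoxp3Th17 than Treg, 347 and 340 in Treg than Th0, 284 the same way by Th17 conditions and 46 by origin. Under quantile normalization and equal medians the share of calls that were higher fell from 50.7% to 45.5% and 46.1% in exFoxp3Th17 versus Th17, whose balance turned at most other settings too, and from 53.2% to 48.4% and 47.3% in exFoxp3Th17 versus Treg; in Treg versus Th0 it rose from 52.9% to at most 61.0%. Signals near the floor limit the counts, and single arrays limit all of them. No paired analysis was possible because each group has 1 array.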

Other observations

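The gene lists in this part were chosen after the data were seen; the test of the interferon-gamma list without its GTPases was chosen only after the result was seen, and the hypoxia list and the full interferon-gamma list were tested as set beforehand.

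Genes induced by hypoxia through HIF-1 formed a further group. In Th17 compared with Th0, 8 of 13 measured targets were higher and 5 neither (median 1.19), among them Vegfa (4.5-fold, 79.5 against 17.8) and Bnip3 (3.4-fold, 2837 against 822.9). In exFoxp3Th17 compared with Th17, 11 of 13 were lower and 2 neither (median -2.25), Bnip3 by 10.8-fold. The hypothesis that HIF-1 targets are higher as a group in Th17 than Th0 predicted a median above the middle 95% of random lists, and it lay at percentile 100. The list was prompted by hypoxia genes among those highest in Th17 and holds other targets. Both were read on the same pair of arrays, so the percentile extends that observation and does not test it independently. The list was also higher in Treg than Th0, 6 of 13 with 7 neither (median 0.90, percentile 100), and lower in exFoxp3Th17 than Treg, 10 of 13 with 3 neither (median -1.77). Hif1a itself was at 1224 in Th0, 4162 in Th17, 2639 in exFoxp3Th17 and 3006 in Treg. The rise over Th0 was thus not confined to Th17 conditions or to the IL-17 positive gate, and its cause was not tested.

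Interferon-gamma response genes were read because Iigp1 (28.0-fold higher in Treg than Th0) and other interferon-inducible GTPases were higher in Treg. The list lay at percentile 99.99 in Treg compared with Th0, with 4 of 12 genes higher and 8 neither (median 0.70). This cannot tell whether the response is higher as a group, because all 4 called genes, among them Igtp (3.7-fold, 3292 against 885.5) and Irgm1 (2.6-fold), are GTPases of the class that prompted the list. Without the GTPases none of 8 genes was called, and the median of 0.33 lay at percentile 98.42. In the same Treg and Th0 pair, type I interferon response genes had 7 of 14 lower and 7 neither (median -0.93). Th1 genes had 5 of 12 higher, 1 lower and 6 neither (median 0.85). Interferon-gamma signalling was not measured.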
